A study of Homo sapiens with 6 samples.

How the data were processed

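RNA-seq of poly-A selected RNA was available for 6 samples of MCF7, an established human breast carcinoma line. Per the labels, all carried a short hairpin RNA against TRIM24 and were rescued with wild type TRIM24 or with a double mutant of its SUMO sites, with 3 samples of each. Nothing in the labels says that the samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

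The authors deposited a table of raw read counts per gene, in whole numbers, for 53598 Ensembl genes. The submitters' processing notes name CASAVA, Bowtie and edgeR and the builds hg19 and GRCh37, with no role and no version. The counting program, the annotation release and the use of strand are not given in the sources used here, so reads of overlapping, antisense and near-identical genes could have been divided in ways the table does not show. The authors also deposited a normalized signal for 32101 genes, with a symbol and a biotype. Set against the counts, this signal was the raw count multiplied by 1 factor per sample, and division by that factor gave whole reads for 100% of the values within 0.01. The rule by which genes were left out of that table is not given in the sources used here. It keeps 61 genes with 0 reads in all 6 samples, and 10216 of its genes have no symbol. Gene symbols and biotypes were taken from it.

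Counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its defaults, which left 24295 of the 38333 genes with at least 1 read, and libraries were scaled by TMM. The double mutant rescue was compared with the wild type rescue by the quasi-likelihood F test in its form before version 4, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are given as log2 of double mutant over wild type rescue with a standard error, which was the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM, the counts scaled to library size after TMM, as mean ± SD over 3 samples. Total reads per sample ran from 64086101 to 72688352. Intervals from read counts cover counting error only.

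A set of 28 gene lists was fixed before the data were examined. They were extracellular matrix, matrix remodelling enzymes, fibroblast markers, mesenchymal and EMT genes, cell-cell junctions, cell adhesion molecules, integrins and focal adhesion, luminal epithelial genes, basal and myoepithelial markers, endothelial markers, haematopoietic cell markers, oestrogen response, retinoic acid response, p53 targets, interferon-stimulated genes, NF-kB and inflammatory genes, SUMO conjugation, TRIM24 family and complex partners, cell cycle and proliferation, replication-dependent histones, mitochondrially encoded genes, TCA cycle and oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol and fatty acid synthesis, glycolysis and hypoxia, unfolded protein and amino acid stress response, heat shock response, and immediate early genes. Each list was tested against the other genes with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. Chosen after the data were seen, the share of members past the threshold in either direction was compared with that of the other genes by Fisher's exact test among genes with a mean of at least 1 CPM, with Benjamini-Hochberg adjustment over the lists.

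The genes named were TRIM24, then the 12 with the largest log2 fold change in each direction among those past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol, and then up to 4 members of each list with the smallest p. This rule was also fixed before the data were examined, and other genes are said to have been chosen after their values were seen.

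The tests were first run on simulated counts drawn from the means, library sizes and dispersions of the 24295 genes, with 200 genes changed by known folds. Alternatives planned before the data were examined were RLE, upper quartile and library total scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, edgeR's exact test, the replicate number as a block, each sample left out in turn, limma on the authors' signal at a pseudocount of 1 or 0.5, and stricter thresholds. Alternatives chosen after the data were seen were the newer quasi-likelihood method, an offset for GC content and transcript length, the reads recovered from the authors' signal, and a test of only those genes whose exons overlap no other gene. GC content, length, exon overlap and gene order came from GENCODE release 29, which is on a newer build than the one the notes name. No coordinates are given for that reason. Genes were matched by Ensembl ID, and 211 of the genes tested whose ID had been replaced were matched by symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.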

Results

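The transcriptome of MCF7 cells was measured by RNA-seq after knockdown of TRIM24, a chromatin reader and transcriptional co-regulator, and re-expression of the wild type protein or of a double mutant of its SUMO sites. The comparison asks which transcripts depend on SUMO modification of TRIM24, among them genes of cell adhesion. Each group held 3 samples. The wild type rescue samples had 64209772, 72688352 and 68294683 reads in genes, and the double mutant rescue samples had 68271125, 64086101 and 70047193. Every pair of libraries differed by more than the sampling noise of reads, with a chi-square per degree of freedom of at least 3.58, so no libraries were merged, which does not show that they came from separate cultures. The first principal component, with 31.2% of the variance, placed all wild type samples on one side and all double mutant samples on the other. The second component, with 22.7%, set wild type replicate 3 and double mutant replicate 2, at -22.0 and -19.9, apart from the other samples, at -1.89 to 17.1.

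TRIM24 itself (ENSG00000122779) was read at 88.5 ± 1.74 CPM in the wild type rescue and at 109 ± 6.72 CPM in the double mutant rescue (SD, n = 3 each). The log2 fold change was 0.30 ± 0.048 (SE), with an adjusted p of 0.0076 in edgeR's quasi-likelihood test. All 3 double mutant samples lay above all 3 wild type samples. The counts do not separate the endogenous transcript from the rescue transcript, and without samples before rescue the extent of knockdown was not measured. Every difference between the groups therefore stands beside a difference in TRIM24 level.

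In the double mutant rescue 307 genes were higher and 260 were lower than in the wild type rescue, of 24295 tested (edgeR quasi-likelihood test, adjusted p below 0.05). The changes were small. The median absolute log2 fold change of the 567 changed genes was 0.32, and 13 higher and 5 lower genes reached a 2-fold change. Protein-coding genes made up 247 of the higher and 228 of the lower genes. All 567 had no overlap between the groups, which held for 22.6% of the genes tested against 10% by chance. The counts rested on individual samples. They fell to 64 higher and 64 lower without double mutant replicate 3, to 92 and 87 without wild type replicate 1, to 120 and 141 without double mutant replicate 1, to 185 and 167 without wild type replicate 2, and to 201 higher genes without double mutant replicate 2. Of the 77 named genes past the threshold, 32 stayed past it whichever sample was left out. Camera called 11 of the 28 fixed gene lists at its preset correlation and 0 with an estimated correlation, and it called 3 to 12 lists in the other splits of the 6 samples into 3 and 3, in which both rescues are mixed.

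Among changed genes with a symbol and a mean of at least 1 CPM, one of the largest increases was that of CYP26B1 (ENSG00000003137), which encodes an enzyme that breaks down retinoic acid. It went from 0.645 ± 0.104 to 1.67 ± 0.271 CPM, a log2 fold change of 1.36 ± 0.19 (SE, adjusted p = 0.0035, edgeR). MUC16 (ENSG00000181143), the mucin that carries the CA125 antigen, went from 5.46 ± 0.570 to 11.2 ± 1.14 CPM. The sialyltransferase gene ST6GALNAC5 rose by 1.35 on the log2 scale, FAM65C by 1.07, the endoplasmic reticulum gene REEP1 by 0.88, the zinc finger gene ZNF804A by 0.85 and the anoctamin ANO7 by 0.84. ADRA2A, an adrenergic receptor, rose by 0.82, ADPRH by 0.78, the axon guidance ligand SLIT1 by 0.76, HEG1 by 0.76 and the endopeptidase PHEX by 0.75. CYP26B1, MUC16, ST6GALNAC5, REEP1, ANO7 and ADRA2A stayed past the threshold with each sample left out. FAM65C, ADPRH and PHEX lost it without wild type replicate 1 or double mutant replicate 1 or 3, ZNF804A and SLIT1 without double mutant replicate 3, and HEG1 when any sample but wild type replicate 3 was left out, with adjusted p up to 0.13 for FAM65C, 0.079 for ADPRH, 0.11 for PHEX, 0.060 for ZNF804A, 0.051 for SLIT1 and 0.14 for HEG1. FAM65C also lost it in DESeq2.

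Among changed genes with a symbol and a mean of at least 1 CPM, the largest decreases were in ACE2 (ENSG00000130234), the membrane carboxypeptidase, which went from 1.86 ± 0.10 to 0.820 ± 0.222 CPM, and in the interferon-inducible gene IFI27 (ENSG00000165949), which went from 13.6 ± 0.684 to 6.97 ± 0.966 CPM. Their log2 fold changes were -1.18 ± 0.19 and -0.97 ± 0.094 (SE). PADI3, which encodes a peptidylarginine deiminase, had a log2 fold change of -0.96, and GJA1, which encodes the gap junction protein connexin 43, one of -0.94. The 9 UGT1A entries tested, which share exons and are 1 locus of glucuronosyltransferases, were all lower, with log2 fold changes of -0.89 to -0.86. Their levels went from 14.7 to 18.2 CPM in the wild type rescue to 8.09 to 9.81 CPM in the double mutant rescue, and reads of the shared exons cannot be assigned to 1 entry. XIST (ENSG00000229807), the long RNA of X inactivation, had the smallest p of all genes, with a log2 fold change of -0.86 ± 0.054 (SE, adjusted p = 1.8e-05, edgeR), and went from 49.8 ± 1.67 to 27.4 ± 1.61 CPM. ACE2, IFI27, PADI3, GJA1, XIST and the named UGT1A entries stayed past the threshold with each sample left out.

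**Figure D1:**
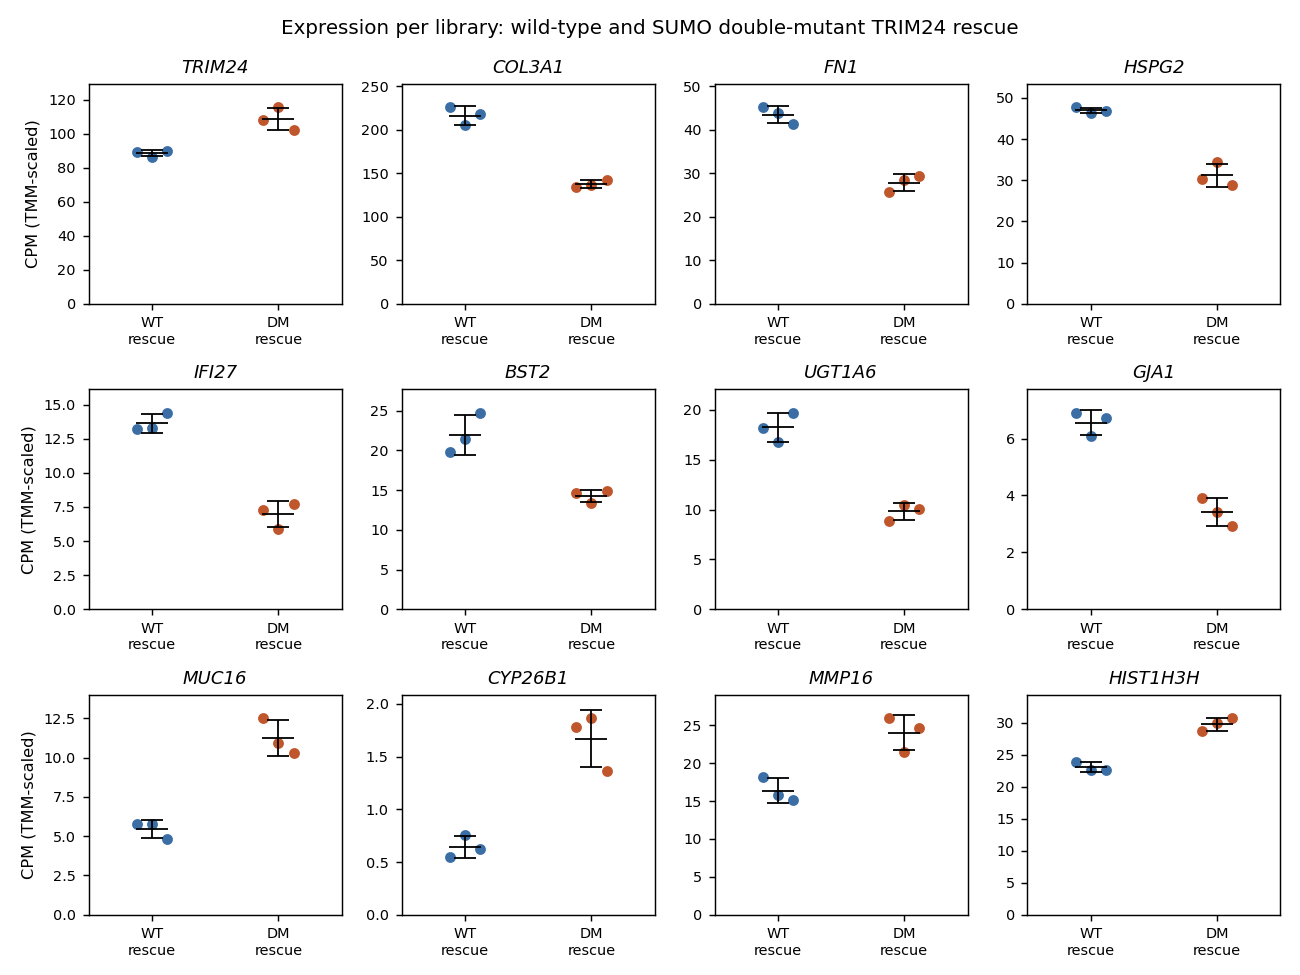
Levels of 12 named genes in each library, in CPM after TMM scaling, with points for the 3 samples of each rescue and bars for mean and SD. TRIM24 lay at 88.5 CPM on average in the wild type rescue and at 109 CPM in the double mutant rescue, and in each panel the groups did not overlap.

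**Figure D2:**
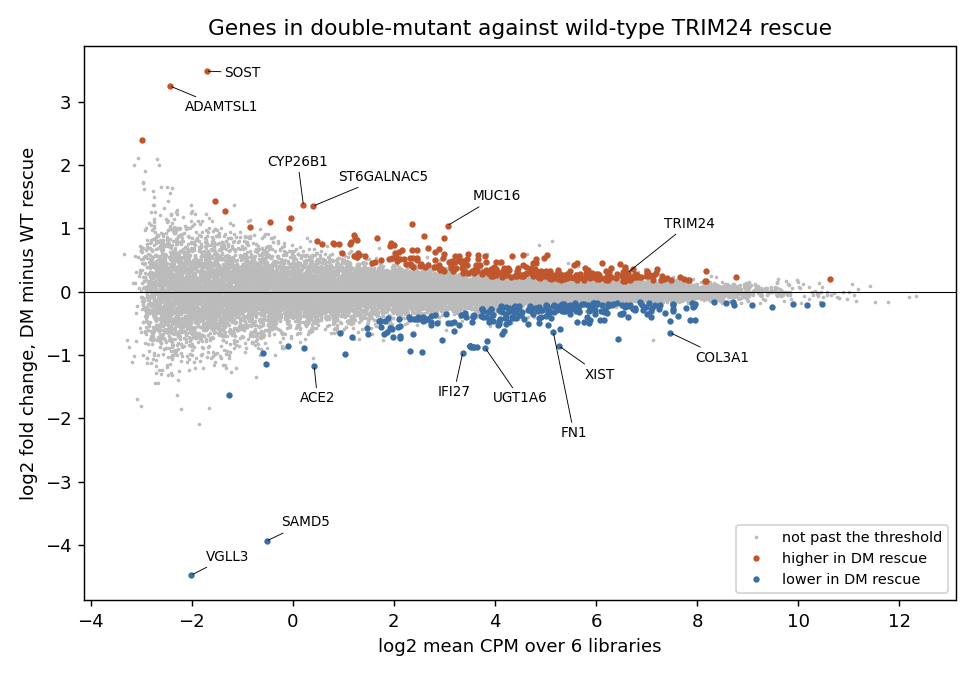
Log2 fold change of double mutant over wild type rescue against log2 of the mean CPM over the 6 libraries, with a point for each of the 24295 genes tested. The 307 higher and 260 lower genes (adjusted p below 0.05, edgeR) are coloured, and most lie within 1 log2 unit of 0. SAMD5, VGLL3, SOST and ADAMTSL1 were labelled after their values were seen.

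More genes of the extracellular matrix fell than rose in the double mutant rescue. COL3A1, a fibrillar collagen and the second gene by p, went from 216 ± 10.5 to 138 ± 4.57 CPM, a log2 fold change of -0.65 ± 0.046 (SE, adjusted p = 3.6e-05, edgeR). Fibronectin, FN1, went from 43.5 ± 1.94 to 27.8 ± 1.94 CPM, and perlecan, HSPG2, from 47.0 ± 0.717 to 31.2 ± 2.81 CPM. The laminin chain LAMC1 fell by 0.26 on the log2 scale. Of 43 matrix genes tested, 2 were higher and 7 lower over all genes, and 6 were higher and 13 lower adjusted over the list alone. Among all 43, 17 log2 fold changes were positive and 26 negative, with a median of -0.085 and a mean of -0.031. The groups overlapped in the mean of the list, taken around that of all 6 libraries in log2 units. It was -0.013 in wild type replicate 2 and -0.010 in double mutant replicate 2, and highest in wild type replicate 3 (0.059). Camera placed the list lower than other genes at an adjusted p of 9.4e-05. This call was lost with an estimated correlation (adjusted p = 0.37), and among genes with no exon overlap, where fewer members were tested (adjusted p = 0.096). COL3A1, FN1 and HSPG2 stayed past the threshold with each sample left out, and LAMC1 lost it without wild type replicate 1 or double mutant replicate 3 (adjusted p up to 0.084).

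Among 42 matrix remodelling enzymes and their inhibitors, 1 was higher and 4 were lower, or 2 and 13 adjusted over the list alone. The protease inhibitor SERPINA1 fell by 0.40 on the log2 scale, TIMP2, an inhibitor of metalloproteinases, by 0.49 and the inhibitor SERPINA3 by 0.26, while the membrane metalloproteinase MMP16 rose by 0.55. The list was lower at an adjusted p of 5.6e-04 in camera and not with an estimated correlation (adjusted p = 0.37). TIMP2 lost its call without double mutant replicate 3 (adjusted p = 0.063), and SERPINA3 without wild type replicate 1 or 2 or double mutant replicate 3 (adjusted p up to 0.11). Of 9 fibroblast markers tested, COL3A1 and FBLN1 were lower and COL6A3 higher, at log2 fold changes of -0.65, -0.47 and 0.41. The list shares 18 of its 22 listed genes with other lists. Its median was -0.12 and its mean was 0.00082, so they differ in sign, and its camera call (lower, adjusted p = 0.047) was lost with an estimated correlation (adjusted p = 0.49), without wild type replicate 1 or 3 or double mutant replicate 1 or 3, among genes with no exon overlap (adjusted p = 0.32), and without a filter on low counts, where the adjusted p was 0.52 and the median 0.15. FBLN1 lost its call without wild type replicate 1 or double mutant replicate 1 or 3 (adjusted p up to 0.067), and COL6A3 without double mutant replicate 1 (adjusted p = 0.065). Of 28 mesenchymal and EMT genes, COL3A1 and FN1 were lower and none was higher, with camera at an adjusted p of 0.14. Adjusted over the list alone 4 were higher and 5 lower.

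Of 59 interferon-stimulated genes, 10 were lower in the double mutant rescue and 0 were higher, or 15 lower and 1 higher adjusted over the list alone. IFI27 had the largest change of the 4 named. BST2, which encodes the antiviral membrane protein tetherin, fell by 0.62 on the log2 scale, and LGALS3BP, a secreted glycoprotein, went from 82.3 ± 1.91 to 60.4 ± 3.19 CPM. UBE2L6, which encodes the conjugating enzyme for ISG15, fell by 0.46 on the log2 scale. The median of the list was -0.07, and camera gave an adjusted p of 2.9e-06 that was lost with an estimated correlation (adjusted p = 0.37). The mean of the list in double mutant replicate 1 (0.031 around the mean of all 6 libraries, in log2 units) lay above that in wild type replicates 1 and 3 (0.0019 and 0.029), the highest was in wild type replicate 2 (0.116) and the lowest in double mutant replicate 2 (-0.148). Without the latter the median of the interferon-stimulated genes was 0.0030. These 4 genes stayed past the threshold with each sample left out. Of 27 NF-kB and inflammatory genes, the complement gene CFB and the lipocalin gene LCN2 were lower, each by 0.48 on the log2 scale, and 0 were higher. Adjusted over the list alone 5 were lower and 1 was higher. The call of this list (adjusted p = 0.029) was lost with an estimated correlation (adjusted p = 0.37), without wild type replicate 1 or 2 or double mutant replicate 3, at a CPM of at least 1 in 3 samples (adjusted p = 0.055) and among genes with no exon overlap (adjusted p = 0.29). CFB stayed past the threshold with each sample left out, and LCN2 lost it without wild type replicate 1 or double mutant replicate 1 or 3 (adjusted p up to 0.063).

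Replication-dependent histone genes were the 1 list that camera placed higher in the double mutant rescue. Of 51 genes tested, 48 had a positive log2 fold change, with a median of 0.25, and 7 were higher over all genes or 23 adjusted over the list alone, with 0 lower in either. HIST1H3H went from 23.0 ± 0.770 to 29.7 ± 1.02 CPM, HIST1H2AI rose by 0.51 on the log2 scale, HIST1H2BF by 0.50 and HIST1H2AC by 0.24. The adjusted p was 3.2e-14 in camera and 0.37 with an estimated correlation. Genes of the same histone family are similar in sequence, and reads could have been divided among them, so the value of any 1 of them is uncertain. HIST1H3H stayed past the threshold with each sample left out, HIST1H2AI lost it without double mutant replicate 3, HIST1H2BF without double mutant replicate 1 or 3, and HIST1H2AC without wild type replicate 2 or double mutant replicate 1 or 3, with adjusted p up to 0.070, 0.082 and 0.13. Of 61 cell cycle genes, 6 were lower and 0 higher, or 21 and 4 adjusted over the list alone. The cyclin CCNA2 fell by 0.23 on the log2 scale, the mitotic kinesins KIF20A and KIF4A by 0.22 and 0.28, and the spindle gene HMMR by 0.19. Camera gave an adjusted p of 6.1e-04, or 0.54 with an estimated correlation and 0.052 among genes with no exon overlap. Each of these 4 calls was lost without wild type replicate 1 or double mutant replicate 1 or 3, and those of KIF4A and HMMR also without wild type replicate 2 or double mutant replicate 2, as was that of KIF20A without double mutant replicate 2, with adjusted p up to 0.096 for CCNA2, 0.14 for KIF20A, 0.15 for KIF4A and 0.16 for HMMR.

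All 13 mitochondrially encoded genes had a negative log2 fold change, with a median of -0.14, or -0.086 without wild type replicate 1. The mean of the list, around that of all 6 libraries in log2 units, was 0.155 in that sample, 0.052 and -0.0088 in the other wild type samples and -0.087 to -0.033 in the double mutant samples. The respiratory chain gene MT-ND6 passed the threshold over all genes, from 1232 ± 36.8 to 1069 ± 50.3 CPM, and 7 were lower adjusted over the list alone. MT-ND2, MT-ND5 and MT-ND4 had log2 fold changes of -0.18, -0.16 and -0.17 and did not pass over all genes. Camera gave an adjusted p of 1.3e-06, or 0.47 with an estimated correlation. Mitochondrial reads made up 3.01% to 3.31% of the wild type and 2.88% to 2.98% of the double mutant libraries. MT-ND6 lost its call without wild type replicate 1 or 2 or double mutant replicate 1 or 3 (adjusted p up to 0.15). Lists of nuclear genes for metabolism and protein synthesis were also placed lower by camera. None of 59 cytosolic ribosomal protein genes passed over all genes or over the list alone (camera adjusted p = 0.0035, or 0.76 with an estimated correlation). Their median log2 fold change was -0.050, and the members of smallest p included RPL5 at -0.15 and RPL21 at -0.24. The groups overlapped, with a list mean of -0.018 in wild type replicate 2 and 0.015 in double mutant replicate 2. None of 47 genes of the TCA cycle and oxidative phosphorylation passed either (camera adjusted p = 0.027, or 0.47 with an estimated correlation). Their median was -0.034, and the members of smallest p included IDH1 at -0.19, IDH3A at -0.15 and PDHB at 0.14. Of 40 genes of the unfolded protein and amino acid stress response, the chaperone gene HSP90B1 was lower, by 0.19 on the log2 scale, and NUPR1 higher, by 0.41 (list adjusted p = 0.0088, or adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 3 were lower and 1 was higher. The median of the stress list was -0.057. Without wild type replicate 1 all 3 lists lost their call, the ribosomal list lost it without double mutant replicate 3, the stress list without wild type replicate 2, and the TCA cycle and stress lists among genes with no exon overlap (adjusted p of 0.056 and 0.24). HSP90B1 and NUPR1 lost theirs without wild type replicate 1 or double mutant replicate 1 or 3, and HSP90B1 also without wild type replicate 2 or double mutant replicate 2, with adjusted p up to 0.23 and 0.19.

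Genes of adhesion between cells moved in both directions. Of 42 cell-cell junction genes, CTNND2, a catenin, and CDH18, a cadherin, were higher by 0.57 and 0.59 on the log2 scale and GJA1 was lower, and GJB2 had a log2 fold change of -0.66 without passing. Adjusted over the list alone 2 were higher and 2 lower. Among 39 cell adhesion molecules, ASTN2 rose by 0.35, the co-receptor NRP1 by 0.27 and CEACAM5 by 0.29, with 0 lower, or 3 higher and 5 lower adjusted over the list alone. L1CAM had a value of -0.20 and did not pass. Of 45 genes of integrins and focal adhesion, PARVA, which encodes parvin alpha, rose by 0.31 and the tensin gene TNS4 fell by 0.53, while ITGA5 had a value of -0.40 and CAV1 one of 0.23 and neither passed. Adjusted over that list alone 2 were higher and 2 lower. Camera called none of these 3 lists, with adjusted p of 0.82 for junctions, 0.93 for adhesion molecules and 0.40 for integrins. GJA1 and TNS4 stayed past the threshold with each sample left out. CTNND2, CDH18, ASTN2, NRP1 and CEACAM5 lost it without wild type replicate 1 or double mutant replicate 1 or 3 (adjusted p up to 0.15), CDH18, NRP1 and CEACAM5 also without double mutant replicate 2, and PARVA without double mutant replicate 3 (adjusted p = 0.066).

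Lists of nuclear receptor and p53 targets, which hold genes tied to known partners of TRIM24, were not called by camera, which asks for a shift in one direction. Of 58 oestrogen response genes 5 were higher and 4 lower (adjusted p = 0.54), or 8 and 7 adjusted over the list alone. CYP26B1 had the largest change, the fatty acid elongase ELOVL2 went from 255 ± 11.3 to 320.4 ± 21.6 CPM, BCAS1 rose by 0.34 on the log2 scale and SERPINA1 was lower. The list shares 21 genes with other lists. By the share of members past the threshold in either direction, a test chosen after the data were seen, it exceeded the other genes with a mean of at least 1 CPM (9 of 58 members, and 552 of all 19140 such genes, Fisher's exact test, adjusted p = 3.6e-04), as did the lists of extracellular matrix, interferon-stimulated genes, replication-dependent histones, fibroblast markers, matrix remodelling enzymes and cell cycle. That test takes genes as independent. Of 31 retinoic acid response genes CYP26B1 and DEPTOR were higher and the retinoid-binding gene CRABP1 was lower, by 0.51 on the log2 scale, and STRA6 had a value of -0.46 without passing (list adjusted p = 0.53). Adjusted over the list alone 4 were higher and 3 lower. Of 47 p53 targets PLK2 and TP53I3 were higher, by 0.22 and 0.46, and none was lower over all genes or over the list alone (adjusted p = 0.96). None of 26 TRIM24 family members and partners passed in either count (adjusted p = 0.42), with values of 0.10 for TRIM28 and -0.17 for TRIM16, and none of 26 SUMO conjugation genes did (adjusted p = 0.083), with values of -0.16 for PIAS3 and -0.12 for SUMO1. ELOVL2 and CYP26B1 stayed past the threshold with each sample left out. BCAS1 lost it without wild type replicate 1 (adjusted p = 0.059), CRABP1, DEPTOR and TP53I3 without double mutant replicate 3 (adjusted p of 0.055, 0.066 and 0.078), and PLK2 without wild type replicate 1 or double mutant replicate 1 or 3 (adjusted p up to 0.086).

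The lists of luminal, basal, haematopoietic and endothelial markers were not called by camera. Of 38 luminal genes, NAT1 and KIAA1324 were higher, by 0.25 and 0.23 on the log2 scale, and the mucin MUC1 went from 183 ± 8.94 to 145 ± 15.2 CPM (list adjusted p = 0.081). Adjusted over the list alone 5 were higher and 2 lower. None of 21 basal and myoepithelial markers passed over all genes, with 2 higher and 1 lower over the list alone (adjusted p = 0.41). Of 9 haematopoietic markers tested CD68 was lower, from 18.1 ± 5.30 to 10.6 ± 2.21 CPM (list adjusted p = 0.40), and of 7 endothelial markers EGFL7 was lower, by 0.32 (list adjusted p = 0.18). Over the list alone the haematopoietic list had 2 higher and 3 lower genes and the endothelial list 1 lower. Among 36 genes of cholesterol and fatty acid synthesis ME1, a malic enzyme, was lower by 0.30 and PMVK higher by 0.20 (list adjusted p = 0.14), or 3 higher and 1 lower over the list alone. Of 45 glycolysis and hypoxia genes KDM3A and the glucose transporter SLC2A1 were higher, by 0.23 and 0.19 (list adjusted p = 0.56), or 3 higher and 1 lower over the list alone. Of 38 immediate early genes MYC rose by 0.26, DUSP2 by 0.43 and CSRNP1 by 0.25 (list adjusted p = 0.21), or 4 higher and 4 lower over the list alone. HSPB8 was lower by 0.22 among 25 heat shock genes (list adjusted p = 0.64), and it was the 1 gene past the threshold over the list alone. ME1 stayed past the threshold with each sample left out. MYC lost it without double mutant replicate 1 or 3, and the other genes named here with a call lost it without 3 or more samples, among them wild type replicate 1 for each, with adjusted p up to 0.22. CD68 also lost it in DESeq2, CSRNP1 and PMVK in limma-voom, PMVK with library totals, KIAA1324 with RLE scaling and at a CPM of at least 1 in 3 samples, and PMVK and KIAA1324 on the authors' signal at either pseudocount.

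**Figure D3:**
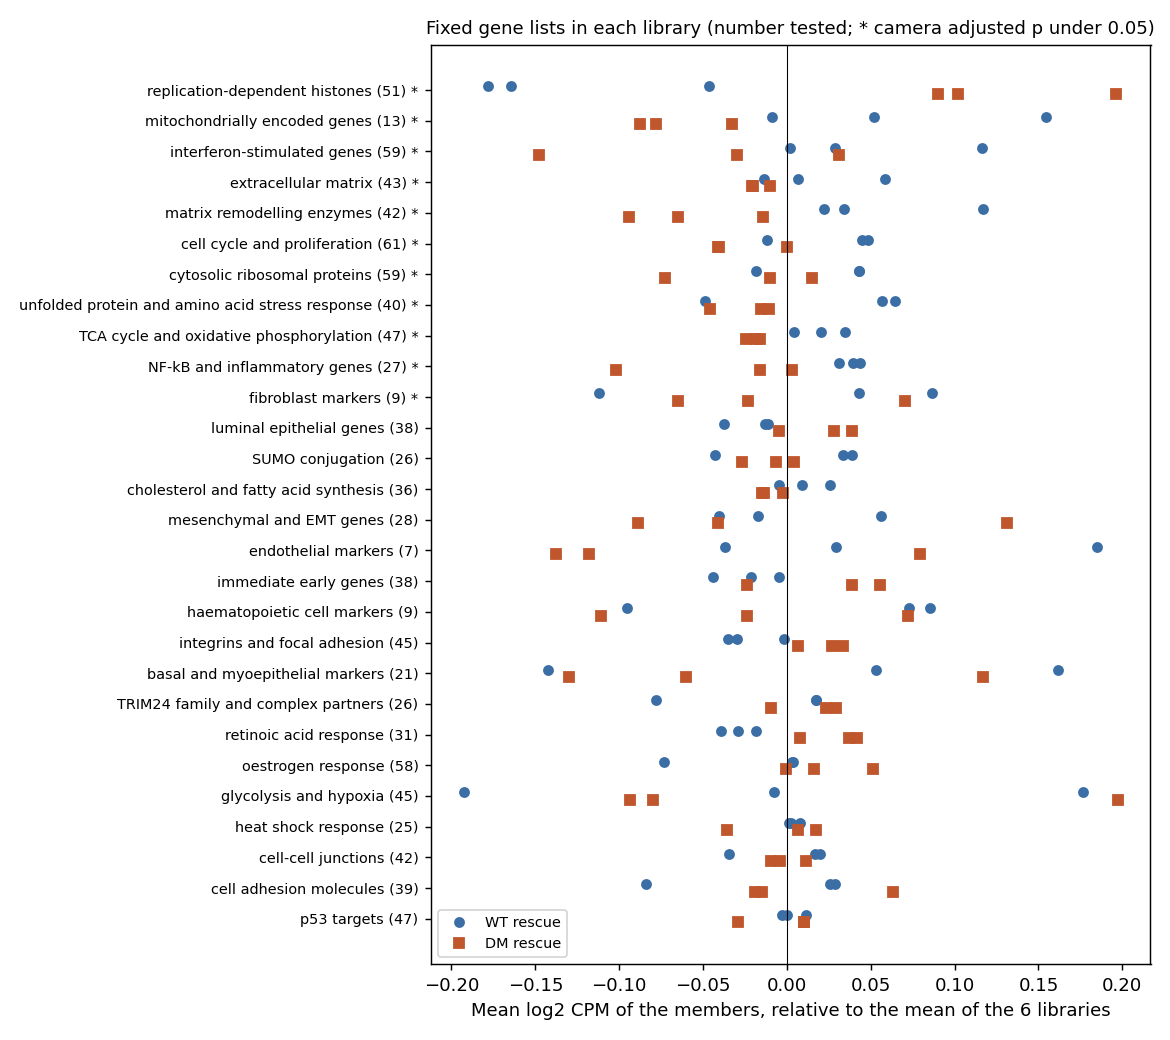
Mean log2 CPM of the members of each of the 28 fixed lists in each library, relative to the mean of the 6 libraries, with circles for wild type and squares for double mutant rescue and the number of genes tested in parentheses. Stars mark the 11 lists called by camera at a preset correlation, of which 0 were called with an estimated correlation. Of these 11, the histone, mitochondrial, matrix remodelling, NF-kB and TCA cycle lists had no overlap between the groups, and the other 6 did overlap.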

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

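The newer quasi-likelihood method, the GC and length offset, the reads recovered from the authors' signal and the restriction to genes without exon overlap were chosen after the data were seen. The main results were 307 higher and 260 lower genes, a TRIM24 log2 fold change of 0.30 and 11 of 28 lists. TRIM24 kept its direction and its call in each alternative fit, and with each sample left out its log2 fold change ran from 0.25 to 0.34. RLE scaling gave 308 and 252 genes, upper quartile 340 and 232, library totals 322 and 246, limma-voom 297 and 261, and the authors' signal 291 and 259 or 257. The reads recovered from that signal gave 307 and 260. Counts moved by over 1.5 times without a filter on low counts (812 and 790), with DESeq2 (493 and 438), with edgeR's exact test (695 and 593), with the GC and length offset (522 and 459, with 557 of the 567 genes shared), among genes without exon overlap (188 and 146, with fewer genes tested), at an adjusted p below 0.01 (73 and 73) and at a log2 fold change of at least 1 (13 and 5). Except where fewer genes or a stricter threshold account for it, the cause was not tested. With each sample left out, counts ran from 64 to 390 higher and from 64 to 352 lower genes, and 6 to 13 lists. With the replicate number as a block there were 148 higher and 138 lower genes and 10 lists, and ASTN2, CCNA2, CSRNP1, DUSP2, EGFL7, HEG1, HMMR, HSP90B1, HSPB8, KIAA1324, KIF20A, KIF4A, MT-ND6, NAT1, NRP1, NUPR1, PHEX, PMVK, SLC2A1 and the fibroblast list lost their calls. Same-numbered samples correlated at 0.078, -0.099 and -0.034 in their deviations from the group means. Differently numbered samples ran from -0.13 to 0.16. These values gave no sign of pairing by number and cannot exclude it. The list calls fell from 11 to 0 with an estimated correlation and to 0 with fry in one direction, while fry in either direction called 25. Among genes without exon overlap they fell to 5, where the matrix, cell cycle, TCA cycle, stress, NF-kB and fibroblast lists lost theirs. Fewer members of the lists were tested there, so these losses do not show that overlapping reads caused the calls. The NF-kB and fibroblast lists lost their calls in limma-voom and on the authors' signal, where the SUMO conjugation list gained one. At a CPM of at least 1 in 3 samples the NF-kB list lost its call and the mesenchymal list gained one. SUMO conjugation and luminal genes also gained one in DESeq2 and, with endothelial markers, without a filter on low counts. The median of the fibroblast list was positive without a filter on low counts (0.15) and in DESeq2 (0.153), and that of the interferon list without double mutant replicate 2 (0.0030), where camera still placed it lower. Medians of called lists moved by over 1.5 times when a sample was left out for every called list but the histone and TCA cycle lists, as they also did without a filter on low counts, in DESeq2 and among genes without exon overlap for the matrix list, in the last of these for the interferon list, and with the GC and length offset for the NF-kB list. HSP90B1 lost its call under upper quartile scaling. The glycolysis and hypoxia list, not called in the main test, had a median log2 fold change between -0.089, without double mutant replicate 2, where it was lower (adjusted p = 0.040), and 0.127, without wild type replicate 3, where it was higher. Its mean was high in those same samples (0.177 in wild type replicate 3 and 0.197 in double mutant replicate 2, and below 0 in the others), which also stood apart on the second component and were the only ones in which genes of high GC content lay above those of middle GC content (by 0.083 and 0.078). Whether that trend or the biology of the cultures raised the list was not tested. In simulated data of this depth the test recovered 66% of genes changed by 25%, 90% of those changed 1.5-fold and 98% of those changed 2-fold, and 10.2% of its calls were false, so many changes of the size seen here would be missed. Of the 10 splits of the 6 samples into 3 and 3, the real one gave 307 higher and 260 lower genes and the highest other gave 1. For lists, every split gave calls, so they also arise when the rescues are mixed. The other splits gave 3 to 12, and 2 splits, the real one included, gave at least 11. The highest other, with 12, had wild type replicates 1 and 3 and double mutant replicate 2 on one side. These splits are too few for a share under 0.05.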

Other observations

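The GC and length tests, the low-count test and the TRIM24 level test were chosen after the results they measure were seen. The bootstrap intervals below resample genes and not samples. They take genes as independent and leave out the spread between samples.

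Outside the fixed lists and chosen after their values were seen, several further genes differed between the rescues. The imprinted long RNA H19 (ENSG00000130600) went from 108 ± 2.54 to 64.4 ± 7.65 CPM, a log2 fold change of -0.75 ± 0.067 (SE, adjusted p = 2.3e-04, edgeR). The transcription factor SOX3 went from 41.5 ± 0.601 to 56.8 ± 1.38 CPM, and the immunoglobulin superfamily gene IGSF1 from 269 ± 12.4 to 198 ± 5.23 CPM. KEAP1, which encodes the adaptor that targets the transcription factor NRF2 for degradation, had a log2 fold change of 0.25 ± 0.039 (SE, adjusted p = 0.0064).

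A further 5 genes were nearly silent in one rescue and read at a low level in the other, again chosen after their values were seen. They were the genes past the edgeR threshold with a log2 fold change of at least 2 in either direction. Each had a mean below 1 CPM over the 6 samples, so the ratios below rest on few reads. SAMD5 had 268 reads over the wild type and 17 over the double mutant libraries, and VGLL3, a cofactor of TEAD factors, had 98 and 4. SOST, which encodes the Wnt antagonist sclerostin, had 114 reads over the double mutant and 10 over the wild type libraries, ADAMTSL1 had 69 and 7, and ENSG00000223718, which has no symbol, had 43 and 8. Scaled for depth, the ratios were 15.6 for SAMD5 (95% interval 9.53 to 27.1), 24.2 for VGLL3 (9.14 to 90.5), 11.6 for SOST (6.06 to 24.7), 9.99 for ADAMTSL1 (4.60 to 25.8) and 5.45 for ENSG00000223718 (2.53 to 13.4), covering counting error only.

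For the 5 nearly silent genes, a binomial test compared the reads in each rescue. Its p was multiplied by the 24295 genes tested, since these genes were picked from all of them. The highest corrected p was 0.0084, for ENSG00000223718, and it covers counting error only. The edgeR adjusted p, which takes in the spread between libraries, was 3.7e-04 for SAMD5, 9.4e-04 for VGLL3, 0.0025 for SOST, 0.0037 for ADAMTSL1 and 0.026 for ENSG00000223718. These genes had been picked by that edgeR test, so small values in either test were bound to follow. They are no independent evidence against chance values of low counts. In these genes the lowest library of the expressing rescue, with 86, 28, 32, 19 and 13 reads in the order above, stood above the highest of the other rescue, with 13, 2, 7, 3 and 4. A lack of overlap between the groups was shared by all 567 changed genes. The loss or gain of a chromosome segment that takes in neighbouring genes was argued against by the 50 neighbours tested. Their median log2 fold change in the direction of the gene was -0.028 (95% bootstrap interval -0.080 to 0.042). Taken gene by gene, the median of the 10 neighbours ran from -0.11 for SAMD5 to 0.036 for ADAMTSL1. A segment too short to reach these neighbours would not be seen. Across the genome, the neighbours of the 321 of 567 changed genes that had no exon overlap and a place in the reference had a median of 0.0084 (0.0040 to 0.014) in the direction of the gene. In 200 random sets of as many genes it was 0.0020 on average and 0.0094 at most. The value lay below the 0.05 set as the bound for copy number differences between the lines, though near the highest of the random sets. As a median over all these neighbours, it cannot show copy number differences behind a minority of the changed genes. The labels do not say whether each rescue came from 1 selected population, so a difference between populations other than TRIM24 stays open, as does the mutation itself.

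For the higher replication-dependent histone genes, less complete poly-A selection was predicted to raise snRNA, snoRNA and misc_RNA genes as well. The 156 tested had a median log2 fold change of -0.029 (95% bootstrap interval -0.069 to 0.0095) against 0.25 for the histones, so they were not raised. These RNAs are short and many lie inside other genes, so their reads need not follow those of histone mRNA. The test therefore cannot decide the question. The offset for GC content and transcript length took away a median of -0.0040 (-0.0078 to 0.0036) of the change of the 51 histone genes, all of which had a GC value, so that trend did not account for it. A larger share of cells in S phase could not be told apart from other causes, since the 51 genes of DNA replication and the G1/S transition had a median of 0.040 (-0.020 to 0.055). The mutation stays open as well.

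For the lower extracellular matrix genes, fewer fibroblasts mixed into the cultures were argued against by COL1A1, COL1A2, DCN, LUM and POSTN, whose median in the wild type rescue was at most 0.016 CPM in any library. COL1A1 was at 40.6 CPM, but COL1A2 was at 0.044 CPM. The offset for GC content and transcript length took away a median of -0.012 (95% bootstrap interval -0.014 to -0.0047) of the fall of the 7 lowered matrix genes, whose median went from -0.59 to -0.60 and which all kept their call. The level of TRIM24 could not be told apart from the mutation, since the lowest double mutant sample lay 12.4 CPM above the highest wild type sample and no samples had matched levels.

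Lower output of the NRF2 programme was tested as a hypothesis. UGT1A, AKR1C1 (log2 fold change -0.31), AKR1C2 (-0.30), ABCC3 (-0.40), ME1 (-0.30) and TRIM16L (-0.22), which are known or proposed NRF2 targets, were lower, a grouping made after their values were seen. The prediction was then set on 22 other NRF2 targets before their values were seen. The 20 tested had a median log2 fold change of -0.13 (95% bootstrap interval -0.15 to -0.090), and 17 of 20 were negative. The median lay beyond the bound of -0.1 set beforehand, though the interval took in that bound. Among the negative values were -0.16 for NQO1 and -0.17 for TXNRD1. The positive values were 0.029 for GCLC, 0.035 for AKR1C3 and 0.23 for ABCC2. None of the 20 passed the threshold alone (edgeR, adjusted p below 0.05). In camera the unadjusted p of the list was 7.8e-06 at the preset correlation and 0.011 with an estimated one. With an estimated correlation the unadjusted camera p was 0.017 for the extracellular matrix list and 0.026 for the histone list. Those lists were not called after adjustment, which the NRF2 list did not undergo. At the preset correlation camera also called lists in splits that mix the rescues. The mean of the NRF2 list lay between 0.038 and 0.094 in the wild type libraries and between -0.060 and -0.051 in the double mutant libraries, in log2 units around the mean of all 6. A modestly lower NRF2 output in the double mutant rescue may therefore be followed up. The higher TRIM24 level, and a difference between the rescue populations other than TRIM24, stay open as alternatives to the mutation.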
